A study of Capra hircus with 5 samples.

How the data were processed

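RNA was measured in 5 libraries of cultured goat cells, 2 of goat ear fibroblasts (GEF) and 3 of goat mammary epithelial cells (GMEC), isolated from goat milk according to the series title. Per the labels' protocols, ribosomal RNA was removed from total RNA with a kit made for human, mouse and rat RNA, cDNA was primed with random hexamers, and libraries were sequenced on an Illumina HiSeq 2500. Such libraries hold RNA with and without a poly(A) tail. Both cell types were grown at 37.5 °C in 5% CO2 in media of their own, per the labels' protocols. The study names GEF as the control group. The labels do not say whether libraries of one cell type came from separate animals or cultures, so p-values measure the spread between these libraries, which may be technical.

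The authors deposited FPKM values (fragments per kilobase of transcript, scaled to the fragments of the library) in 2 tables, one per gene and one per transcript, with a column per library. The submitters' processing notes name FastQC 0.10.1, HTSeq and DESeq2 1.16.1 without saying what each was used for. The aligner, assembler, genome build and annotation are not given in the sources used here. The gene table has 30317 rows. Of these, 28920 carry identifiers made of the word gene and a number, called annotated loci here, and 1211 carry MSTRG identifiers, the default prefix of the assembler StringTie, called assembled loci here. The remaining rows have the prefixes id (162 rows) and rna (24 rows). The transcript table has 62805 rows, of which 9364 are assembled. In the deposited tables, 100% of the gene FPKM values lay within 0.05 of the sum of the gene's transcript FPKM values. FPKM are not counts, and they come without counts, lengths or depths. Sequencing depth is therefore unknown, no counting interval can be given, and no whole-read steps could be read from the low values, which are rounded to the hundredth.

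Neither table pairs its identifiers with gene names. None of the gene identifiers (0) and none of the transcript identifiers (0) matched any entry of the goat gene table used for names (assembly ARS1.2), and names were not inferred from the order of the identifiers. The 32 lists of marker and pathway genes chosen before the data were examined could therefore not be tested, and no gene is named beyond its identifier. At most 2 identifiers per direction are printed for the comparison of cell types.

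The comparison was fitted with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with cell type as the only term and an intensity trend in the variance. Loci with at least 1 FPKM in at least 2 of the 5 libraries were tested, 13692 genes and 25702 transcripts. A locus passed at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Unequal change of the transcripts of one gene was tested with limma's diffSplice and Simes p-values per gene. Summary values per library were compared with a two-sided exact permutation test, whose smallest possible p with 2 against 3 libraries is 0.2, so it could not pass 0.05.

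The rule for naming genes, fixed beforehand, took the largest fold changes among genes past the test whose libraries did not overlap between cell types, with a mean of at least 10 FPKM in the higher cell type and a gene symbol. Since no symbol is known, the 2 annotated loci with the largest change in each direction stand in for it. The rule's parts on list members, on the most abundant genes and on transcripts by name could not be applied.

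The procedures were tested on simulated data drawn from the observed means and residual spreads. Noise was independent between loci, with the same spread in both cell types. In the tests of genes and transcripts, changed loci were not drawn from the lowest or highest mean levels. In the real data the GEF libraries differed less than the GMEC libraries, and GMEC replicate 1 stood apart over many genes. The rates below therefore hold for a simpler setting than these data. For genes (13692 simulated), 75% of genes changed by 1.5 on the log2 scale and 92% of those changed by 3 were recovered, with 2 false calls. For transcripts (25702 simulated), 46% and 68% were recovered, with 9 false calls. For transcript usage (6154 genes simulated), 38% and 86% were recovered, but 45 unchanged genes were called too, so the usage calls are less reliable. A test with a variance per transcript on the same simulated data made 0 false calls and recovered 10% and 65%; its count is given beside the diffSplice count.

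Alternatives fixed beforehand were a pseudocount of 0.1, no filter, a filter of 5 FPKM, rescaling to a common sum (TPM), median-of-ratios scaling, quantile normalization, other variance models, the replicate number as a block, the lane label as a covariate, the L004 libraries alone, other fold thresholds, and leaving out each library. Fits with fewer libraries were first run with the filter applied again to the libraries left. After those counts were seen, the loci that passed the filter in all 5 libraries were kept instead, because a filter of 2 libraries removes loci expressed in GEF alone once only 1 GEF library is left. Alternatives added after seeing the data were that second filtering, weights per cell type, leaving out assembled loci, leaving out loci listed at 0 in one library and at 5 FPKM or more in another of the same cell type, averaging the 2 GEF libraries into 1 sample, and the usage test with a variance per transcript.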

Results

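Gene expression was profiled in goat mammary epithelial cells (GMEC), the cells that line the milk-producing alveoli and ducts and are shed into milk, and in goat ear fibroblasts (GEF), connective tissue cells grown from the ear. The GMEC were obtained from milk and compared with fibroblasts as the control, in a study on isolating and identifying such cells. There were 3 GMEC and 2 GEF libraries. Cell type coincides with tissue of origin and culture medium, and the labels do not give the animals. Descriptions of the libraries carry the lane label L004 for both GEF libraries and GMEC replicate 1, and L002 for GMEC replicates 2 and 3.

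The values were FPKM without counts, so the depth of each library is unknown. Summed FPKM lay between 671012 and 773394 per library. Of the 30317 gene loci in the table, 20451 had a value above 0 in at least 1 library and 9866 were listed at 0 throughout. GMEC libraries had 12455 ± 67.4 loci at 1 FPKM or more (SD, n = 3), and GEF libraries had 12751 ± 1.41 (SD, n = 2). The 100 most abundant loci took 38.8% ± 1.44 of summed FPKM in GMEC and 34.9% ± 0.462 in GEF. The single most abundant locus took 3.47% ± 0.0838 in GMEC and 1.87% ± 0.218 in GEF. For each of these 3 measures the GMEC and GEF libraries did not overlap, and the two-sided exact permutation p was 0.2, the smallest this design allows.

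The cell type was the main axis of variation. The first principal component of log2(FPKM + 1) over the 13692 tested genes held 87.7% of the variance and separated the 2 GEF from the 3 GMEC libraries. The second held 7.71% and set GMEC replicate 1 against GMEC replicates 2 and 3. Across genes, the correlation of the GEF libraries with each other was 0.992, that of GMEC pairs was 0.967 for replicates 1 and 2, 0.972 for replicates 1 and 3 and 0.985 for replicates 2 and 3, and that between cell types was 0.796 to 0.821. These are correlations across genes, which are not independent replicates. The median absolute log2 difference between the GEF libraries was 0.068, against 0.132 to 0.288 between GMEC libraries and 0.426 to 0.638 between cell types.

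The first comparison asked which genes were expressed at different levels in mammary epithelial cells and fibroblasts. In GMEC, 1402 genes were higher and in GEF 1737 were higher, together 22.9% of the 13692 tested (limma, Benjamini-Hochberg adjusted p under 0.05 and at least 2-fold). The median change among them was 1.66 on the log2 scale for genes higher in GMEC and -1.58 for genes higher in GEF. Large differences were about as frequent on both sides. A change of at least 4-fold on the log2(FPKM + 1) scale was reached by 507 genes higher in GMEC and 588 higher in GEF, and one of at least 64-fold by 35 and 30. Another 132 genes had a 2-fold or larger difference that did not pass the test. The median change over all tested genes was -0.08, and rescaling each library to the same sum moved it to -0.19, so that 1354 genes were higher in GMEC and 2092 higher in GEF. Median-of-ratios scaling gave 1530 and 1571, and quantile normalization turned the order, with 1573 higher in GMEC and 1510 higher in GEF. Within the 3 libraries with the lane label L004 (1 GMEC and 2 GEF), 1662 genes were higher in GMEC and 2428 higher in GEF, but GMEC is then 1 library assumed to vary like the GEF libraries, the closest pair, and the label L002 was on GMEC libraries alone. The count of genes higher in GEF depended on how the filter was applied when a GEF library was left out. It was 1395 without GEF replicate 1 and 1432 without GEF replicate 2 on the same loci, but 753 and 784 when the filter was applied again to the libraries left, which removes loci expressed in GEF alone.

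**Figure D1:**
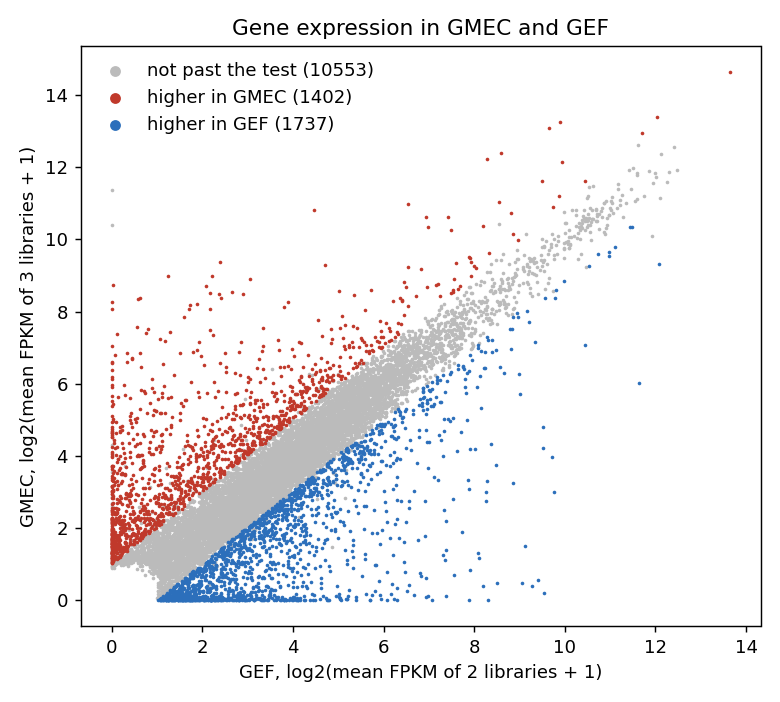
Each point is 1 of the 13692 tested genes, plotted by log2 of its mean FPKM plus 1 over the 2 GEF libraries (x axis) and over the 3 GMEC libraries (y axis), with colour for the limma result. Most genes lie along the diagonal, 1402 lie above it as higher in GMEC, 1737 lie below it as higher in GEF, and both sets include genes near 0 in one cell type.

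The genes that dominated each transcriptome were largely shared. Of the 100 most abundant genes in GMEC, 76 were also among the 100 most abundant in GEF, and 72 of these 76 did not pass the test. The other 4 shared genes were higher in GMEC. Among the 100 most abundant in GMEC, 18 were higher in GMEC and the other 82 did not pass. Among the 100 most abundant in GEF, 10 were higher in GEF, 4 were higher in GMEC and 86 did not pass. On the deposited scale, the larger count on the GEF side came from genes under 10 FPKM. With both cell types weighted equally in the mean level, a weighting chosen after the data were seen, 641 genes were higher in GMEC and 976 higher in GEF at 1 to 10 FPKM, and 109 and 145 under 1 FPKM. At 10 to 100 FPKM the counts were 549 and 521, and at 100 FPKM or more 103 and 95. By the mean over all 5 libraries, which places genes of the cell type with more libraries higher, they were 577 and 478, and 119 and 82, in these 2 ranges. Counts by level were not repeated after other scalings. GMEC replicate 1 read low at low levels, with a median log2 ratio to replicates 2 and 3 of -0.229 and -0.231 at 1 to 10 FPKM. At 1000 FPKM or more these ratios were 0.201 and 0.017. Without GMEC replicate 1, 1383 genes were higher in GMEC and 1620 higher in GEF.

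A smaller set of genes was close to on or off by cell type. In GMEC, 100 loci were at 10 FPKM or more in every GMEC library and under 1 FPKM in both GEF libraries. In GEF, 126 loci showed the opposite pattern. Assembled loci made up much of the GMEC set, which fell to 47 without them, while the GEF set was 122 without them. Among 895 loci at 100 FPKM or more in both GEF libraries, 22 stayed below 1% of their mean GEF level in every GMEC library, and 9 of these below 0.1%. Among 837 loci at 100 FPKM or more in all 3 GMEC libraries, 18 stayed below 1% of their mean GMEC level in both GEF libraries, and 4 of these below 0.1%.

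The 2 annotated loci with the largest change in each direction were at over 100 FPKM in one cell type and under 1 FPKM in the other. The locus gene11355 was at 429, 454 and 405 FPKM in GMEC replicates 1 to 3, at 0.05 FPKM in GEF replicate 1 and listed at 0 in GEF replicate 2, a log2 fold change of 8.71 (SE 0.091, limma adjusted p = 5.91e-06). The locus gene24332, with 31 listed transcripts, was at 324 ± 39.5 FPKM in GMEC (SD, n = 3) and 0.49 ± 0.014 in GEF (SD, n = 2), a log2 fold change of 7.76 (SE 0.13). In the other direction, gene19399 was at 0.147 ± 0.042 FPKM in GMEC and 747 ± 1.28 in GEF, a log2 fold change of -9.35 (SE 0.095). The locus gene17424 was at 0.293 ± 0.118 FPKM in GMEC and 621 ± 0.148 in GEF, a log2 fold change of -8.91 (SE 0.12). The files used here do not pair these identifiers with gene names or positions. The 12 annotated loci with the largest changes in each direction ranged from 5.66 to 8.71 on the GMEC side, with GMEC means of 49.5 to 666 FPKM. On the GEF side they ranged from -7.06 to -9.35, with GEF means of 134 to 747 FPKM.

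**Figure D2:**
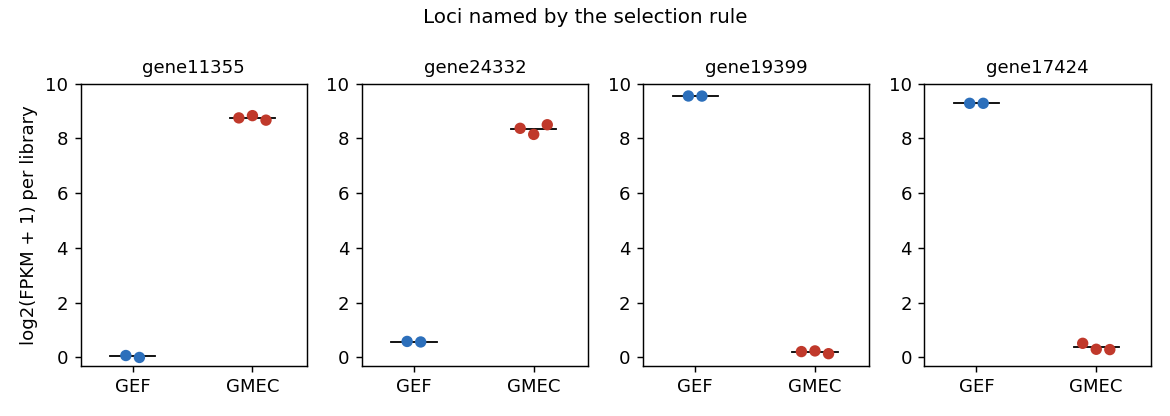
Points are single libraries, plotted as log2(FPKM + 1) on the y axis for the 4 named loci (1 panel each), with GEF in blue and GMEC in red, and black lines at the mean of the log2 values of each cell type. In each panel the means of the 2 cell types differ by at least 7.76 on this log2 scale while libraries of a type lie close together.

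The second comparison separated annotated loci from loci that the deposited table lists under assembler identifiers. Assembled loci differed between cell types more often than annotated loci, and mostly by being higher in GMEC. Of 987 tested assembled loci, 43.2% passed the test, 340 higher in GMEC and 86 higher in GEF. Of 12700 tested annotated loci, 21.4% passed, 1062 higher in GMEC and 1651 higher in GEF (Fisher's exact test, two-sided, on passing or not, odds ratio 2.80, p = 9.32e-49, across loci, which are not independent replicates). Without the assembled loci the fit called 1064 genes higher in GMEC and 1656 higher in GEF. Assembled loci held 6.28% ± 0.421 of summed FPKM in GMEC and 4.88% ± 0.188 in GEF (exact permutation p = 0.2, the smallest possible). The excess on the GMEC side was largest at the end of the assembler's numbering, which runs to 16785. Of 285 tested loci numbered above 16000, 187 were higher in GMEC and 12 higher in GEF, against 153 and 74 of 702 loci with lower numbers. The boundary at 16000 was set after the values were seen. The 187 loci had a median level of 14.7 FPKM in GMEC and 0.195 FPKM in GEF. Together they took 1.17%, 2.08% and 1.78% of summed FPKM in GMEC replicates 1 to 3, and 0.030% and 0.033% in the GEF libraries.

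**Figure D3:**
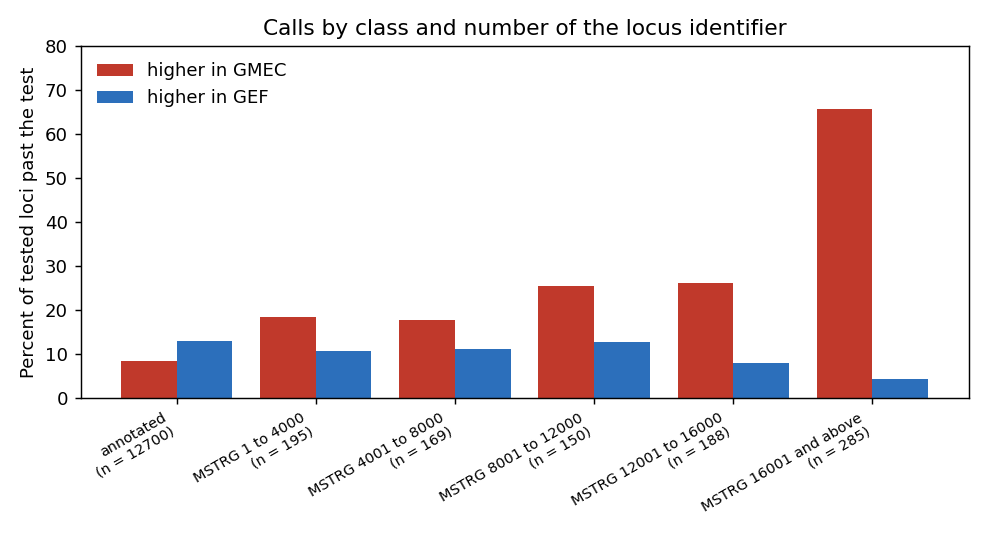
Bars give the percent of tested loci past the test (y axis) as higher in GMEC (red) or higher in GEF (blue) for annotated loci and for assembled loci in 5 ranges of their identifier number (x axis, n tested below each). Loci numbered above 16000 stand out, with 65.6% higher in GMEC and 4.21% higher in GEF, against 8.36% higher in GMEC among annotated loci.

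The third comparison asked which transcripts differed and whether transcripts of one gene changed unequally. At the transcript level, 2572 transcripts were higher in GMEC and 2716 higher in GEF, 20.6% of the 25702 tested (limma, adjusted p under 0.05 and at least 2-fold). The order turned with median-of-ratios scaling (2706 and 2547), quantile normalization (2759 and 2584) and a pseudocount of 0.1 (3139 and 2892). Rescaling to TPM widened the difference, with 2580 higher in GMEC and 3229 higher in GEF. In 130 genes, at least 1 transcript was higher in GMEC and at least 1 other was higher in GEF. Of these genes, 103 did not pass the test at the gene level, 13 were higher in GMEC and 14 higher in GEF. The transcript counts were lower without either GEF library, at 1334 and 1624 without GEF replicate 1 and 1358 and 1650 without GEF replicate 2 on the same loci, and 1155 and 455 or 1153 and 462 with the filter applied again.

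The transcript with the highest level differed between cell types in a part of the genes. Among 8748 tested genes with several listed transcripts, 5635 had the same leading transcript in all 5 libraries. In 458 genes the 3 GMEC libraries shared one leading transcript and the 2 GEF libraries shared another. The same count for the other ways of splitting the libraries into 3 and 2 was at most 181. No minimum level was required in either cell type, so a gene near 0 in one cell type can count with a leading transcript that means little. Such genes arise mainly in the real split, so the 458 and 181 are not a like-for-like comparison. How many of the 458 were of this kind was not counted. By diffSplice, 1358 of 6154 genes (22.1%) showed unequal change of their transcripts between cell types at an adjusted p under 0.05. Of these, 980 did not pass the test at the gene level. The other 378 did, among them gene24332, gene19399 and gene17424. On the log2(FPKM + 1) scale, low transcripts change less than abundant ones when a whole gene changes. A gene with a low transcript, or one that falls near 0, can therefore show unequal change without a shift in usage. This can also affect genes that changed by less than 2-fold, among them genes of the 980. For such genes the call cannot be told from that effect, and in the simulated data no whole gene changed. On simulated data diffSplice also called 45 unchanged genes, so its count is less reliable than the others. It fell to 455 without GEF replicate 1 and 492 without GEF replicate 2 (178 and 194 with the filter applied again), and to 502 with the replicate number as a block. A test with a variance per transcript called 922 genes, of which 706 were among the 1358. It works on the same scale, so the same limit holds for genes with low transcripts and for genes near 0 in one cell type.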

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

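The loci used in fits with fewer libraries, weights per cell type, averaging GEF, leaving out assembled or on-off loci, and the usage test by transcript were chosen after seeing the data, the others before. The 4 named loci passed in all 108 tests that included them, but were picked for the largest changes in these data. On the same loci, gene counts stayed within 1.5 times of 1402 and 1737 under other pseudocounts, scalings and variance models and with any library left out. Both lane settings compare GMEC replicate 1 alone with GEF and say nothing of stability. The filter and threshold moved them by construction: 1154 genes were higher in GEF with a filter of 5 FPKM, 3111 and 3748 were higher in GMEC and GEF with no fold threshold, and 707 and 917 with limma's treat against 2-fold. Applying the filter again to the libraries left was the form first run. It gave 753 to 1950 genes higher in GEF with 1 library left out (784 without GEF replicate 2) and 750 with the GEF libraries averaged (1141 and 1419 genes higher in GMEC and GEF on the same loci), lowest where 1 GEF sample is left, because loci expressed in GEF alone then fail a filter of 2 libraries. The share of calls higher in GMEC was 62.3% without GEF replicate 1 in that form and 45.4% on the same loci. It was 39.3% with TPM, 51.0% with quantile normalization and 44.7% as reported. Transcript counts were 1525 and 1442 with a filter of 5 FPKM, 4126 higher in GEF with the lane label as a covariate (cause not tested), and 1245 and 1639 with the GEF libraries averaged (1086 and 447 with the filter applied again). The L004 libraries gave 2860 and 3903, or 1842 and 4451 with the filter applied again. Leaving out 1 library gave 1334 to 2700 transcripts higher in GMEC and 1624 to 3025 higher in GEF, and 1153 to 2681 and 455 to 3059 with the filter applied again (1155 and 455 without GEF replicate 1, 1153 and 462 without replicate 2). A lone GEF library is then assumed to vary like the GMEC. Transcript usage was called in 594 genes with a filter of 5 FPKM, 502 with the replicate block, 455 to 1730 with 1 library left out and 178 to 1737 with the filter applied again (194 without GEF replicate 2), lowest without GEF replicate 1 and highest without GMEC replicate 1. Same-numbered libraries did not deviate together (correlation of deviations across genes -0.073 for number 1 and -0.040 for number 2). With 2 GEF libraries, their deviations from the mean mirror each other, and these libraries hardly differ. The correlations therefore cannot exclude that same-numbered libraries share an animal or a batch. The replicate block called 1460 and 1843 genes. Without assembled loci, 47 rather than 100 loci were on in GMEC and off in GEF. The alternatives for gene lists were not run, since no identifier could be named. Depth is unknown, so it cannot be said which low values lie near 1 read, and a value listed at 0 sets no limit.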

Other observations

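The tests on the share of assembled transcripts, on transcripts that switch off within a cell type, on consecutive identifier numbers and on other splits were set out before their results were seen, and the others were chosen after. Fold changes of annotated loci with consecutive identifier numbers were correlated across 7157 pairs (Pearson r = 0.196, Spearman rho 0.212), above the highest of 1000 shuffles (0.0384, permutation p = 0.001, the smallest these can give). These are correlations across loci, which are not independent replicates. The correlation was 0.125 at a distance of 2 numbers, 0.060 at 5, 0.032 at 10 and 0.018 at 50. The hypothesis that loci with neighbouring numbers change together, judged by this correlation, was met. Runs of calls were less clear. The longest run of consecutive numbers higher in GMEC was 6 loci, against at most 5 in 100 shuffles. For loci higher in GEF it was 4, against at most 5 in 100 shuffles. Whether the numbers follow the genome, and whether reads shared by overlapping loci add to the correlation, was not tested.

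Loci at the end of the assembler's numbering were mostly higher in GMEC (187 of 285). For an assembly drawn mainly from GMEC reads, a first test met its mark of 20 percentage points. Called assembled transcripts of annotated genes were higher in GMEC 20.4 points more often than called annotated ones (60.3% of 1394 against 40.0% of 3467). The interval of 17.3 to 23.4 includes the mark and treats transcripts as independent, which they are not. Such an assembly may account for a general lean of assembled features. Unannotated transcripts expressed mainly in GMEC would lean the same way, so the test does not tell these explanations apart. Loci numbered above 16000 were higher in GMEC 43.8 points more often than earlier assembled loci, but that boundary was drawn from the same calls, so the difference does not decide whether the assembly accounts for them. For an outside RNA source with a fixed profile, such as another organism, the first test went against it, since the log2 ratio of GMEC replicates 1 and 2 spread 1.57 times as widely in 130 of these loci as in annotated genes at like levels (interval 1.22 to 1.94, mark 1.2). A comparison with 16 earlier assembled loci, added after that result because assembled loci may be measured less precisely, gave 0.968 (interval 0.453 to 2.31), too wide to decide, and the median ratio of the 130 loci was -0.72 against 0.19 in the matched annotated genes (difference -0.90, interval -0.999 to -0.819), which either explanation allows, so such a source and goat loci expressed in GMEC cannot be told apart here.

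GMEC replicate 1 stood apart from replicates 2 and 3: with cell type in the model, 337 genes differed by lane label, against at most 3 when GMEC replicate 2 or 3 was set apart in the same way, which largely restates that replicates 2 and 3 are the closest GMEC pair, since 1 library is compared with that pair. For GEF-like cells in that culture, a first test was undecided and a second, which went against them, is not relied on: the median log2 ratio of replicate 1 to replicates 2 and 3 was -0.03 over 154 genes abundant and higher in GEF (bootstrap interval -0.12 to 0.01), and 54.0% of the 337 genes moved toward GEF, but 81 of the 337 passed the test between cell types, so the others had no established level to move toward. A later test argues against cells with the profile of the GEF libraries for the genes it covers, since the 70 genes that moved toward GEF and passed between GEF and GMEC replicates 2 and 3 would each need at least 6.90% of GEF RNA, while 40 of 891 loci abundant in GEF lay below that level in replicate 1, and 20 of them below 1%. A few very abundant loci shifting the scale by 1 factor per library is argued against too. After median-of-ratios scaling, replicates 1 and 2 still differed 2.22 times as much as replicates 2 and 3 (mark 1.5). The median absolute log2 differences were then 0.295 for replicates 1 and 2, 0.218 for 1 and 3 and 0.133 for 2 and 3. Before scaling they were 0.288, 0.235 and 0.132. At 100 FPKM or more in both GEF libraries and replicate 1, 16 loci were at least 2-fold higher in replicate 1 than in replicates 2 and 3. A shift that changes with level was present, with a median log2 ratio of replicates 1 and 2 of -0.229 at 1 to 10 FPKM and 0.201 at 1000 FPKM or more. About the median of each range, the median absolute deviation was 0.407 and 0.169 for replicates 1 and 2. It was 0.299 and 0.115 for 1 and 3, and 0.190 and 0.078 for 2 and 3. These values argue against a shift between ranges of level as the whole account. A shift within a range was not removed. A difference of sequencing lane or run and a difference between cultures cannot be told apart, because replicate 1 is the only GMEC library with its lane label.

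A pair of assembled loci with consecutive numbers, chosen after their values were seen, was listed at 0 in alternate libraries. MSTRG.1861 was at 3790 and 3941 FPKM in the GEF libraries and 3263 in GMEC replicate 2, and at 0 in GMEC replicates 1 and 3, where MSTRG.1862 was at 4017 and 3877. Their sum varied by 7.93% between libraries (coefficient of variation), less than the median of 14.5% over the 133 loci at 1000 FPKM or more, which is consistent with the same reads having been assigned to one locus or the other. More widely, 389 transcripts of genes with several transcripts were at 0 in one library and at 5 FPKM or more in another of the same cell type. These were 42 of 8379 transcripts at 5 FPKM or more in a GEF library and 347 of 9296 in a GMEC library. With 3 GMEC and 2 GEF libraries, the pattern has more chances to arise in GMEC, so these counts do not compare the cell types. In 78.1% of the 389 transcripts the gene's total stayed within 2-fold, under the 80% set for assignment among transcripts as the explanation, which stays open.

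Of the 10 splits of the 5 libraries into 3 and 2, 1 gave as many genes as the real one, itself, with 3139 genes against at most 3 in any other, and 10 splits are too few for a share under 0.05. The GEF libraries differed less than any GMEC pair in each range of level, with a median absolute deviation of their log2 ratio of 0.118 at 1 to 10 FPKM and 0.027 at 1000 FPKM or more, against 0.190 and 0.078 for GMEC replicates 2 and 3.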
